A study of Escherichia coli with 10 samples.

How the data were processed

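RNA levels of Escherichia coli MG1655 were measured by RNA sequencing in 10 libraries, 3 of wild-type cells, 3 of mfd- cells, 2 of cells with the empty plasmid pCA24N and 2 of cells with pCA24N carrying mfd (Mfd++). Libraries were grouped by their titles and genotype labels. The cells were grown in LB, wild-type and mfd- cells to an optical density (560 nm) of about 0.5, per the labels' protocols. The plasmid strains received 100 µM IPTG for 1 hour from a density of about 0.25, and their density at harvest is not known here. RNA was purified with a column kit and treated with DNase, per the labels' protocols. The aligner, the counting program, its use of strand, the genome build and the annotation are not given in the sources used here.

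For the plasmid strains the authors deposited a table of log2 RPKM (reads per kilobase of gene, scaled to the reads of the library) per gene and library, per the file headers. A blank in that table was read as 0 RPKM. Of its rows, 54 carried 9 repeated names, all insertion sequence genes, and were left out, which left 4442 genes. For mfd- and wild-type cells the authors deposited a table of 46398 bins of 100 bp whose header names log2 RPKM, but the values are log2 of the number of aligned bases in each bin and are not scaled to library size. Raised to the power, they were whole numbers within 0.01 for 99.96% or more of the bins below 3000 bases in each library, the libraries summed to 903 M to 1507 M bases, and reads had 50 bases. The plan to test the bins as deposited was therefore replaced by a test of log2(RPKM + 1), computed from these bases and each library's total, and the values as deposited were kept as an alternative. Columns of means over 3 libraries and 3 neighbouring bins in the deposited log2 values were not used. Gene levels of this experiment were computed as the length-weighted mean RPKM of the bins over each gene, with the gene starts and ends of the authors' gene table. The bins carry no strand, so overlapping and antisense genes cannot be told apart.

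The authors' deposited gene table gives, for 4495 genes, group means and their difference in log2, a t statistic (a score), a −log10 of the unadjusted p-value and an unsigned ratio (fold difference) of mfd- and wild-type cells, per the file headers. From the values, the deposited p-value is that of a two-sided t with 4 degrees of freedom, with 6 genes off by more than 1%. The lists deposited beside it held 351 genes at an unadjusted p under 0.05, of which 191 higher and 36 lower genes had a fold over 1.5, and 119 names without values appended to the higher list were not used. Gene starts were the same for 4442 genes in the tables of both experiments. Gene names matched a RefSeq symbol or synonym for 4482 genes, and no RefSeq coordinate is printed because the builds were not shown to be the same.

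Depth in the first experiment was taken as the sum of bases over 50. In the second, where only RPKM are given, 1 read is the smallest step of RPKM times gene length, and a depth was accepted where at least 95% of the 300 lowest genes came out whole within 0.1 of a read. This held for 96.3% with vector replicate 2, 98.3% with Mfd++ replicate 1 and 96.7% with Mfd++ replicate 2, and for 69.3% with vector replicate 1, whose depth stayed unknown. Ribosomal RNA took 0.115% to 7.90% of the signal of the libraries of the first experiment. A gene of 1 kb at 1 RPKM has 18 to 30 reads in the first experiment, so levels near 1 RPKM carry large counting error.

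Each comparison was fitted on its own libraries with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend, two-sided) on log2(RPKM + 1), over genes with a mean of at least 1 RPKM, with Benjamini-Hochberg adjustment at 0.05. The added 1 RPKM makes fold changes of low genes too small. Levels are given as mean and SD of RPKM over libraries, and mfd was also tested with an exact permutation test of SciPy 1.17.1. For Mfd++ the estimated prior was infinite. The 38 gene lists were fixed before the data were examined, and were tested with camera at a preset correlation of 0.01, camera with an estimated correlation, and fry (statmod 1.5.0), over lists of at least 4 measured members. With an estimated correlation camera rests on the residual degrees of freedom of the libraries, which are few here. It has little power in both experiments, so a list that it does not call is not shown to be unchanged. The change of each list is counted over all genes and adjusted over the list alone. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.

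Genes named in the text were chosen by a rule fixed before the data were examined: mfd, the 10 largest rises and 10 largest falls past the threshold with groups that did not overlap and a mean of at least 10 RPKM, up to 4 members with the smallest p from each list called or holding 3 members past the threshold, and the neighbours of mfd. Of the members that the rule gives for lists that were not called, few are named, and apart from the neighbours of mfd these were picked after their values were seen. Genes outside the rule are said to be so where they are named. For bins, runs of called bins with gaps of at most 1 bin are named. Stretches without reads were searched for after the data were examined, from the log2 ratio of each gene to its control level, with 0.1 RPKM added. They are at least 8 genes over which the median ratio of 7 neighbouring genes lay more than 3 log2 units below the median ratio of all genes.

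The steps were checked on simulated data with 200 changed genes or bins of known fold, drawn with the spread that eBayes gave each gene or bin. In the Mfd++ design, where the prior was infinite, this is the spread that the fit itself assumes. The simulation therefore cannot check whether adjusted p come out too small there. In the mfd- design 25% of 2-fold, 75.8% of 4-fold and 100% of 16-fold changes were called, with 9 false calls among 4491 genes. In the Mfd++ design the shares were 25%, 72.7% and 87.9%, with 7 false calls among 4435 genes, and for the 46300 bins 0%, 47.0% and 86.4%, with 7 false calls. A raised list was called and 0 other lists in both designs. The simulated genes were drawn independently, so this does not check the list test where members of a list vary together. Among splits of the real mfd- experiment, 10 of 10 called at least as many lists as the real groups.

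Alternatives planned before the data were examined were a pseudocount of 0.1 or 10 RPKM, no filter or a filter at 10 RPKM, median centring, quantile normalisation, no trend, the replicate number as a block, and leaving out each library. Added after the data were examined were leaving out replicate 3 of both groups of the first experiment, leaving out the stretches without reads and ydbA, exchanged replicate numbers for Mfd++, and leaving out each library after centring. A planned test of the signal along genes was not made, since it needs the strand of each gene on the build used.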

Results

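RNA was sequenced from cells of Escherichia coli MG1655, a laboratory strain of the K-12 line. The cells had the genotype mfd- or a plasmid carrying mfd, and each was set against its control. Mfd is the transcription-repair coupling factor, a DNA translocase that removes RNA polymerase stalled on DNA and brings in the nucleotide excision repair proteins. The first experiment held 3 libraries of wild-type cells and 3 of cells with the genotype mfd-, grown in LB to an optical density of about 0.5. The second held 2 libraries of cells with the empty expression plasmid pCA24N (vector) and 2 of cells with the same plasmid carrying mfd (Mfd++), both given 100 µM IPTG for 1 hour. Depth in the first experiment ranged from 18.1 M to 30.1 M reads of 50 bases. In the second it was worked out as 23.2 M reads for vector replicate 2, 35.3 M for Mfd++ replicate 1 and 31.5 M for Mfd++ replicate 2, and could not be worked out for vector replicate 1. Nothing in the labels says that libraries of a group came from separate cultures, so every p measures only the spread between these libraries, which may be technical.

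In mfd- cells, mfd fell 24.0-fold, from 108 ± 36.7 RPKM in wild type to 4.49 ± 0.675 (SD, n = 3 each), while yhfY, a gene of uncharacterised function, rose 8.74-fold, from 20.02 ± 4.85 to 175 ± 16.8 RPKM (SD, n = 3 each). These were the only genes of 4491 past the threshold in the limma fit, 1 up and 1 down. The log2 fold change of mfd was -4.26 with a standard error of 0.32 (limma, adjusted p = 0.000771), and that of yhfY was 3.09 with a standard error of 0.27 (limma, adjusted p = 0.00181). The exact two-sided permutation test of the mfd levels gave p = 0.1, the smallest that 3 against 3 allows. At an unadjusted p under 0.05, 404 genes passed, and with single libraries left out 143 to 504 did (limma). In 12.8% of the genes the 3 libraries of one group all lay above those of the other, where chance gives 10%.

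Reads were missing over mfd itself, at 1169741 to 1173187 of the deposited gene table, whose genome build is not given in the sources used here. Of 33 bins of 100 bp that lay wholly inside the gene, 32 fell below 5% of the wild-type level, from 1169901 to 1173100. The 33 bins stood at 109 ± 37.1 RPKM in wild type and 0.528 ± 0.153 in mfd- cells (SD, n = 3 each), a 206-fold fall, and 88.7% of the mfd signal of mfd- cells came from the 2 bins across the ends of the gene. Of these the bin at 1169701 to 1169800 stood at 63.1 RPKM in wild type and 169 in mfd- cells, not past the threshold (limma, adjusted p = 0.434), and the bin at 1173101 to 1173200 at 98.5 and 41.2 RPKM (0.606). The bin test called 33 bins lower, all in the run from 1169801 to 1173100, and 6 bins higher out of 46300. Of the higher bins, 4 lay at 3509001 to 3509400, with log2 fold changes from 2.75 to 3.66. They overlap yhfY, at 3509082 to 3509444, and the first of them lies partly outside it. The other 2 lay at 1653301 to 1653500 in ynfA, which encodes a small membrane protein. Over its whole length ynfA stood at 23.1 ± 2.69 RPKM in wild type and 81.5 ± 7.70 in mfd- cells (SD, n = 3 each), a log2 fold change of 1.77 that missed the threshold (limma, adjusted p = 0.0687) and passed it after median centring (adjusted p = 0.0315). This gene was singled out after its values were seen. Without wild-type replicate 3 the bins called numbered 87. With single libraries left out the higher bins numbered 3 to 6, and with the replicate number as a block 3. In the 5th percentile of all bins, replicate 3 of both groups held more signal, 5.03 RPKM in wild type and 3.77 in mfd-, than the other libraries at 0.995 to 1.42 RPKM. Without replicate 3 of both groups 37 bins were lower and 0 higher by limma, with 3779 at an unadjusted p under 0.05.

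**Figure D1:**
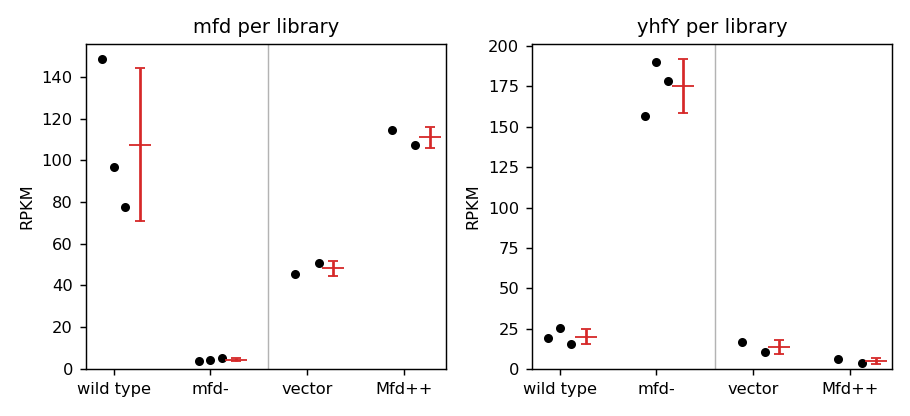
RPKM (vertical axes) of mfd and yhfY in each library of the 4 groups (black points), with the mean and SD of each group (red). The mfd- libraries lie between 3.81 and 5.16 RPKM for mfd, and yhfY is at 157 to 190 RPKM in them against 15.7 to 25.3 in wild type. The grey line parts the 2 experiments, whose levels were normalised separately.

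The genes beside mfd did not pass the test in mfd- cells. The 11 measured neighbours, among them lolC, lolD and lolE of the lipoprotein transport system, nagK and cobB, had log2 fold changes from -0.27 for ycfS to 0.32 for bhsA, and 0 of them passed over all genes, adjusted over the list alone or unadjusted (limma). The genes beside yhfY and ynfA did not pass over all genes, with log2 fold changes from 0.05 for yhfW to 0.93 for yhfZ, so all were above 0. Next to yhfY, yhfZ stood at 30.6 RPKM in wild type and 58.2 in mfd- cells (limma, adjusted p = 0.446), and its unadjusted p was under 0.05. For nucleotide excision repair, 0 of 8 members and for the SOS regulon of DNA damage genes 0 of 33 members passed (limma), with 1 member of each at an unadjusted p under 0.05.

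In mfd- cells, among genes of sugar and alcohol uptake under the catabolite regulator CRP, 0 of 73 passed (limma) over all genes and 5 lower members passed adjusted over the list alone (6 after centring), 20 passed unadjusted, with a median log2 fold change of -0.51. Its members with the smallest p were the maltose transporter genes malK, at 1624 ± 612 RPKM in wild type and 405 ± 100.4 in mfd- cells, and malF, at 477 ± 268 and 97.0 ± 23.7 (SD, n = 3 each). Flagella and chemotaxis genes had a median of -1.05 with 0 of 54 past the threshold on either basis and 19 at an unadjusted p under 0.05 (limma). The flagellar rod genes flgB and flgC stood at 220 ± 77.6 and 221 ± 70.3 RPKM in wild type and 81.7 ± 87.8 and 82.6 ± 89.6 in mfd- cells, where replicate 3 reached 183 and 185 RPKM and the others stayed at or under 42.3. Of 18 genes of the TCA cycle 0 passed over all genes and 5 lower members passed over the list alone (1 after centring), 7 passed unadjusted, with succinate dehydrogenase gene sdhD at a log2 fold change of -1.10 and the fumarase gene fumC at -1.43. In purine and pyrimidine synthesis 0 of 28 passed over all genes and 1 higher member over the list alone, 5 passed unadjusted, and pyrF, of the uridine monophosphate pathway, stood at 76.8 ± 9.49 RPKM in wild type and 202 ± 45.2 in mfd- cells (SD, n = 3 each).

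With the correlation between genes preset at 0.01, camera called 7 of 38 lists in mfd- cells, 3 higher and 4 lower. The lower lists were CRP genes and flagella (adjusted p = 1.12e-12 for each), the TCA cycle (8.92e-05) and the lac operon (0.0289, 4 members, 0 past the threshold and 2 unadjusted, lacZ at a log2 fold change of -0.77). The higher lists were purine and pyrimidine synthesis (8.92e-05), ribosomal proteins (0.00265, 54 members, 0 past the threshold and 2 unadjusted, rpsU at 0.86) and RNA polymerase with its elongation and termination factors (0.0039, 14 members, 0 past the threshold and 3 unadjusted, rfaH at 1.03 and nusG at 0.85). Each of these 7 calls was lost with an estimated correlation, at an adjusted p = 0.995, and fry called 0 of 38 lists, at an adjusted p = 0.973. The loss with an estimated correlation says little, since that test has few degrees of freedom with 3 against 3 libraries. For the lists not called the preset adjusted p ran from 0.0866 for the DLP12 prophage to 0.978. Leaving out wild-type replicate 1 also ended the calls of the lac operon (adjusted p = 0.202), purine and pyrimidine synthesis (0.117) and RNA polymerase (0.0894), and turned the direction of the ribosomal proteins (0.0717). The lac operon was not called without mfd- replicate 3 (0.109), purine and pyrimidine synthesis not without mfd- replicate 2 (0.147), and ribosomal proteins not without mfd- replicate 1 (0.122) or mfd- replicate 2 (0.302). Without wild-type replicate 2 or wild-type replicate 3 the lists called numbered 12 and 14, and without replicate 3 of both groups 15.

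Without wild-type replicate 3, 9 genes passed in mfd- cells: yhfY rose, and mfd, the maltose genes malK, malF, malM and malG, the nucleoside genes cdd and nupG, and yhjX fell. These genes were not called in the fit of all 6 libraries except mfd and yhfY. In that reduced fit malK had a log2 fold change of -2.31 and an adjusted p = 0.0284 (limma). Without replicate 3 of both groups 0 genes passed by limma, with 387 at an unadjusted p under 0.05. In that fit mfd had a log2 fold change of -4.56, yhfY had 2.92 with an adjusted p = 0.234, and the smallest adjusted p was 0.123.

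The authors' deposited table of mfd- against wild type lists 351 genes at an unadjusted p under 0.05, of which 291 were higher and 60 lower in mfd- cells. Chance alone gives 225 of its 4495 genes at that level. The median log2 fold change of that table was 0.10, against -0.01 computed from the bins, an offset that favours higher over lower genes in its list. In that table yhfY was 9.82-fold higher, ynfA 3.84-fold higher and mfd 14.03-fold lower in mfd- cells. After Benjamini-Hochberg adjustment of the p in the authors' deposited table, insE was the 1 gene under 0.05, an insertion sequence gene with several copies whose p did not match its own t statistic. The smallest adjusted p among the others was 0.431. The log2 fold changes computed from the bins and those of the authors' deposited table had r = 0.984 across genes, which are not independent replicates.

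In Mfd++ cells, mfd rose 2.30-fold, from 48.2 ± 3.53 RPKM with vector to 111 ± 5.02 (SD, n = 2 each), a log2 fold change of 1.19 with a standard error of 0.26 (limma, adjusted p = 1.2e-05). The exact permutation test gave p = 0.333, the smallest that 2 against 2 allows. The heat shock genes rose together: 20 of 21 measured members passed upward, among them the small heat shock proteins ibpA, from 22.2 ± 9.45 to 4432 ± 176 RPKM, and ibpB, from 14.8 ± 6.08 to 2477 ± 67.5, and the chaperones dnaK, from 241 ± 4.46 to 5802 ± 359, and htpG, from 87.6 ± 0.658 to 1298 ± 152 (SD, n = 2 each). Genes of anaerobic respiration and fermentation under the oxygen-sensing regulator FNR fell, 45 of 62 members, among them the nitrate transporter gene narK, from 1398 ± 136 to 3.23 ± 0.0246 RPKM, and the nitrate reductase gene narG, from 1212 ± 88.1 to 5.35 ± 0.353 (SD, n = 2 each). The gene with the largest rise, ydbA, a pseudogene interrupted by insertion sequences, went from 140 ± 54.8 to 57206 ± 7686 RPKM (SD, n = 2 each) and took 44.6% and 54.0% of the signal of the Mfd++ libraries, against 0.154% and 0.0875% with vector.

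The median gene of the Mfd++ libraries had a log2 fold change of -1.17. Centring each library on its median gene raised every log2 fold change by 1.35. This left the median log2 fold change at 0.18, so 0 on the centred scale does not mark the median change. On that scale the log2 fold change of mfd was 2.53, that of ydbA 10.06 and that of ibpA 8.99. Counts over all genes, and medians of called lists, are given below on both scales. Levels in RPKM and counts over a list alone are not centred. In the limma fit 140 of 4435 genes rose and 2420 fell, an up share of 5.47%. After centring 702 rose and 594 fell, an up share of 54.2%, and all 140 risen and 594 of the fallen genes passed on both scales. Quantile normalisation gave 730 risen and 722 fallen genes. At an unadjusted p under 0.05, 2704 genes passed without centring. The groups did not overlap in 56.7% of genes after centring and in 78.8% before it, a share that a shift of all genes alike would raise, where chance gives 33.3%. Without vector replicate 2 the risen genes numbered 80 uncentred and 390 centred. Vector replicate 1 had a raised floor, with a lowest value of 2.10 RPKM and a 5th percentile of 6.79 RPKM, against 5th percentiles of 0.393 to 0.807 RPKM in the other libraries of this experiment. With 2 libraries in a group, limma's estimated prior outweighed the genes' own spread, so each gene was judged by the spread common at its level and many adjusted p came out far smaller than 2 libraries can carry. Without the trend, where the smallest adjusted p was 0.00277, 74 genes rose and 1861 fell.

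Other large rises were in aroF and tyrA, neighbouring genes of aromatic amino acid synthesis, from 35.7 ± 5.98 to 2980 ± 323 RPKM and from 37.2 ± 6.12 to 1515 ± 118 (SD, n = 2 each). Also risen were hslV, of a heat shock protease, by 3.59 on the log2 scale (4.93 centred), fhuF, of iron release from siderophores, by 3.46 (4.81 centred), and ycjM, of sugar metabolism, by 3.69 (5.04 centred). Large falls besides narK and narG were in yfiD, which encodes a spare part of pyruvate formate-lyase, from 8883 ± 1474 to 30.3 ± 2.60 RPKM, and ansB, the anaerobic asparaginase, from 878 ± 74.2 to 4.84 ± 0.315 (SD, n = 2 each). The log2 fold change of narK was -8.37 (-7.02 centred) and that of yfiD -8.14 (-6.80 centred). The prophage gene borD fell from 1022 ± 62.0 RPKM to 10.7 and 2.27 in the Mfd++ libraries. In the limma fit without trend ydbA, ibpA and narK had an adjusted p = 0.00277, ycjM 0.00919 and mfd 0.0278.

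Further large falls lay in a stretch of the chromosome where nearly all genes lost their reads in both Mfd++ libraries. From ycjQ to yncI, at 1372987 to 1529663 of the deposited gene table (157 kb, 150 genes), 74 of 82 genes expressed with vector at 10 RPKM or more stayed below 5% of their vector level. The median gene of this stretch kept 1.47% of its vector level in Mfd++ replicate 1 and 0.256% in replicate 2. A shorter stretch from elbB to yhcD, at 3347828 to 3363210 (15.4 kb, 9 genes), kept 1.62% and 0.272%, with 5 of 7 expressed genes below 5%. Outside them 89 of 3133 expressed genes were below 5%, and the median gene kept 42.2% and 40.2%. The long stretch holds uspE, a universal stress protein gene that fell from 399 ± 86.6 to 1.71 ± 1.71 RPKM (SD, n = 2 each), ydcH, and the overlapping genes hokB, mokB and sokB of a toxin system, whose log2 fold changes of -8.18, -8.03 and -8.19 (-6.84, -6.68 and -6.85 centred) are uncertain because the values carry no strand. It also holds fnr and tyrR, the genes of the FNR regulator and of the repressor of aromatic amino acid genes, singled out after their values were seen, with fnr at 357 ± 55.6 RPKM with vector and 4.80 ± 5.12 in Mfd++, and tyrR at 139 ± 12.6 and 1.26 ± 1.26 (SD, n = 2 each). The risen gene ydbA lies inside the long stretch, at 1463416 to 1472037, and ycjM lies just outside it, at 1368240. The same search found no such stretch in the mfd- libraries. Of the genes called, 96 lay in these stretches.

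**Figure D2:**
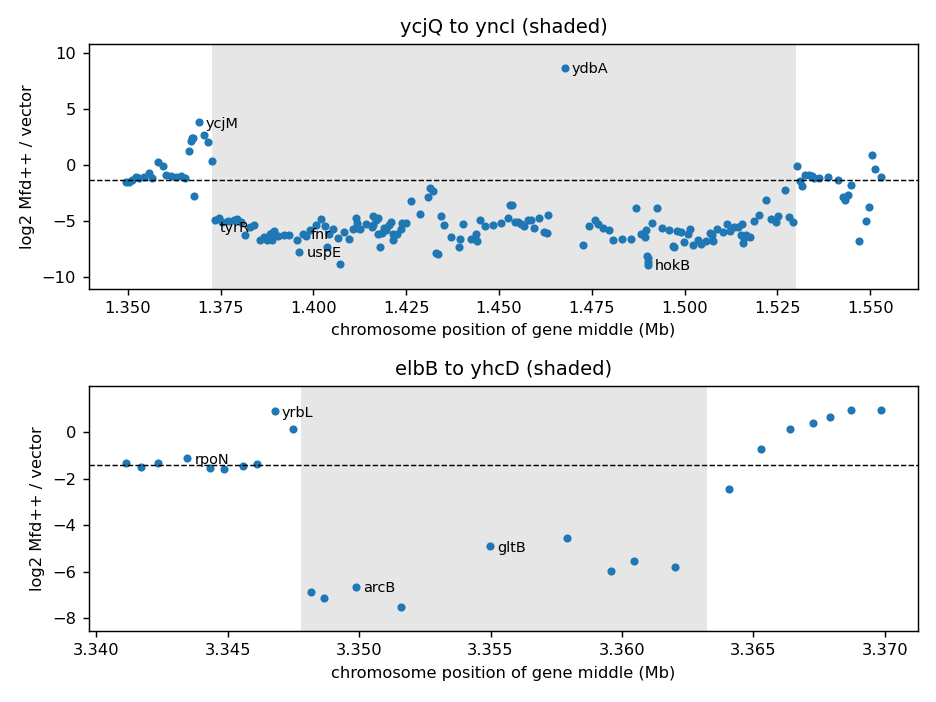
Log2 ratio of the mean RPKM in Mfd++ to that in vector libraries (vertical axis, 0.1 RPKM added to each) against chromosome position in Mb for genes at 1 RPKM or more with vector, around the long (top) and short (bottom) stretch, each shaded. The dashed line is the median of all genes. Nearly all genes of the shaded stretches lie far below the line, and ydbA lies far above it.

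Among heat shock genes in Mfd++ cells 20 of 21 rose and 1 fell over all genes and over the list alone, and centred 20 rose and 0 fell, with a median log2 fold change of 2.96 (4.30 centred). The camera test gave an adjusted p = 7.38e-50 with the preset correlation, and adjusted p = 0.135 with an estimated correlation. FNR genes had 0 risen and 45 fallen of 62, or 1 and 39 centred, with 46 fallen adjusted over the list alone, and a median of -4.49 (-3.14 centred). Their adjusted p was 8.22e-37 preset, and adjusted p = 0.396 with an estimated correlation. The nap nitrate reductase gene napF fell from 685 ± 127 to 6.53 ± 0.576 RPKM (SD, n = 2 each). The gene of the FNR regulator lies in the long stretch.

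In glycolysis 17 of 17 genes fell, or 11 centred, with a median log2 fold change of -2.37 (-1.02 centred), among them pykA and fbaA, with log2 fold changes of -3.30 and -3.07 (-1.95 and -1.73 centred). In CRP-controlled sugar uptake 5 of 73 rose and 55 fell, or 9 and 39 centred, with a median of -2.36 (-1.02 centred), among them the tryptophanase gene tnaA, from 1991 ± 47.5 RPKM to 103 and 22.6 in the Mfd++ libraries, and glpA, of glycerol phosphate use, from 846 ± 80.6 RPKM to 50.8 and 16.04. Adjusted over the list alone, 17 glycolysis genes fell, and 6 CRP genes rose and 56 fell. In aerobic respiration and ATP synthesis 28 of 30 genes fell on both bases, or 12 fell and 2 rose centred, with a median of -2.07 (-0.73 centred), cydA at -2.87 (-1.52 centred) and atpD at -2.56 (-1.21 centred). Preset adjusted p were 1.79e-06 for glycolysis, 6.13e-09 for CRP genes and 1.73e-05 for aerobic respiration, and each had an adjusted p = 0.992 with an estimated correlation. The call of aerobic respiration was also lost after centring (0.079). Without vector replicate 2 the preset calls of glycolysis (adjusted p = 0.113), CRP genes (0.454) and aerobic respiration (0.93) were lost, and with a filter at 10 RPKM those of CRP genes (0.140) and aerobic respiration (0.123).

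Iron uptake genes moved both ways before centring, 13 of 42 rising and 9 falling, and mostly up after it, 29 against 1, with a median log2 fold change of 0.64 (1.98 centred). The siderophore transport gene tonB rose from 21.5 ± 1.996 to 71.3 ± 4.80 RPKM, and feoA, of ferrous iron uptake, fell from 209 ± 78.5 to 45.4 ± 6.34 (SD, n = 2 each), a log2 fold change of -2.13 (-0.79 centred). Adjusted over the list alone 12 rose and 9 fell. In aromatic amino acid synthesis 3 of 18 rose and 9 fell on both bases, and centred 7 rose and 0 fell. There aroL, of the shikimate pathway, rose from 68.6 ± 13.1 to 298 ± 15.4 RPKM (SD, n = 2 each). The median of this list was -0.86 (0.49 centred) and its mean 0.15 (1.49 centred), and the test direction was up. Phage shock genes, which respond to membrane stress, had 5 risen and 2 fallen of 7 on both bases (5 and 1 centred), with a median of 1.03 (2.38 centred) and pspB at 50.1 and 199 RPKM in the Mfd++ libraries against 27.8 ± 8.15 with vector (SD, n = 2), a rise that did not pass without the trend (adjusted p = 0.112) or without vector replicate 2 (limma, adjusted p = 0.151). Its neighbour pspE fell by 2.88 on the log2 scale (-1.53 centred). Preset adjusted p were 2.48e-06 for iron uptake, 0.000158 for aromatic synthesis and 0.00846 for phage shock, and each had an adjusted p = 0.992 with an estimated correlation. Without Mfd++ replicate 2 phage shock was not called (0.781).

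In purine and pyrimidine synthesis 26 of 28 genes fell on both bases, or 13 centred, with a median of -1.98 (-0.64 centred), purC at -2.79 (-1.45 centred) and purA at -2.31 (-0.96 centred). In type 1 fimbriae, the surface fibres of adhesion, 8 of 9 fell on both scales and bases, with a median of -3.004 (-1.66 centred), the main subunit gene fimA going from 1065 ± 143 RPKM to 28.5 and 10.02 and fimI from 105 ± 3.75 to 3.23 ± 1.66 (SD, n = 2 each). All 4 lac operon genes fell, or 3 centred, with a median of -3.10 (-1.75 centred), lacZ from 629 ± 23.4 to 120.5 ± 14.2, a log2 fold change of -2.38 (-1.03 centred), and lacA from 124 ± 3.04 to 3.36 ± 1.42 RPKM (SD, n = 2 each). The repressor gene lacI, which the plasmid also carries, stood at 8160 ± 1401 and 2855 ± 70.4 RPKM (SD, n = 2 each), a change not past the threshold after centring (-0.16) or without vector replicate 1 (-1.33, limma, adjusted p = 0.0606). Preset adjusted p were 0.0206 for purine and pyrimidine synthesis, 0.00846 for fimbriae and 0.00796 for the lac operon, and each had an adjusted p = 0.992 with an estimated correlation. The call of purine and pyrimidine synthesis was lost without vector replicate 2 (0.115), Mfd++ replicate 1 (0.0759) or Mfd++ replicate 2 (0.145), that of fimbriae without Mfd++ replicate 1 (0.0668) or Mfd++ replicate 2 (0.0747), and that of the lac operon without vector replicate 1 (0.0849) or vector replicate 2 (0.326). With a filter at 10 RPKM the calls of fimbriae (0.143) and the lac operon (0.152) were also lost.

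In all, camera called 13 of 38 lists in Mfd++ cells with the preset correlation, 6 higher and 7 lower, and 0 with an estimated correlation. With 2 against 2 libraries the latter could hardly call any list. Even heat shock, with 20 of 21 members risen, had an adjusted p = 0.135 in it. The fry test, which does not set a list against other genes and so takes in the common shift, called 1 list higher and 15 lower. Of the 13 preset calls it kept 7, among them heat shock (adjusted p = 0.00987) and FNR genes (0.00777), and lost 6: aerobic respiration (0.0674), aromatic synthesis (0.135), iron uptake (0.564), phage shock (0.632), colanic acid (0.452) and the Qin prophage (0.275). After centring fry called 4 lists, heat shock (0.00906) and aromatic synthesis (0.0173) higher and FNR genes (0.00906) and fimbriae (0.0153) lower. Without Mfd++ replicate 2 the lists called numbered 8. The remaining called lists were colanic acid capsule, with 0 of 20 past the threshold on either basis or unadjusted, and 0 centred (limma), and the Qin prophage, with 0 risen and 7 fallen of 32 (4 and 0 centred, 4 fallen over the list alone). Both had a preset adjusted p = 0.0443 upward against uncentred medians of -1.07 and -0.86, which centring turned to 0.28 and 0.48, and adjusted p = 0.992 with an estimated correlation. Neither was called after centring (0.93 and 0.385), with a pseudocount of 0.1 RPKM (0.0544 and 0.0571), without Mfd++ replicate 1 (0.0555 and 0.0561) or without Mfd++ replicate 2 (0.0703 and 0.109), the Qin prophage not with a filter at 10 RPKM (0.173), and without vector replicate 2 both turned downward (0.00659 and 0.547). Of the lists not called, the SOS regulon had 0 risen and 24 fallen of 33 (3 and 1 centred), nucleotide excision repair 0 and 7 of 8 (0 and 2 centred), and the neighbours of mfd 0 and 7 of 11 (3 and 0 centred), the counts over the list alone being 24, 7 and 7 fallen. The preset adjusted p of the lists not called ran from 0.0558 for the TCA cycle to 0.987. Centring added calls of the DLP12 prophage (0.00873, lower, 0 risen and 11 fallen of 29, or 1 and 7 centred), the Rac prophage (0.0262, lower, 0 and 7 of 30, or 0 and 7 centred, all 30 in the long stretch) and ribosomal RNA (0.0304, higher, 0 and 7 of 21, or 14 and 0 centred), whose medians were -1.49, -2.35 and -0.13 (-0.15, -1.002 and 1.22 centred). After centring these 3 lists were not called with an estimated correlation (adjusted p = 0.995 for each) or by fry (0.116, 0.116 and 0.286). The ribosomal RNA genes are near-identical copies, so counts of their members are uncertain. Ribosomal RNA took 0.957% and 1.78% of the signal with vector and 1.38% and 1.13% in Mfd++.

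**Figure D3:**
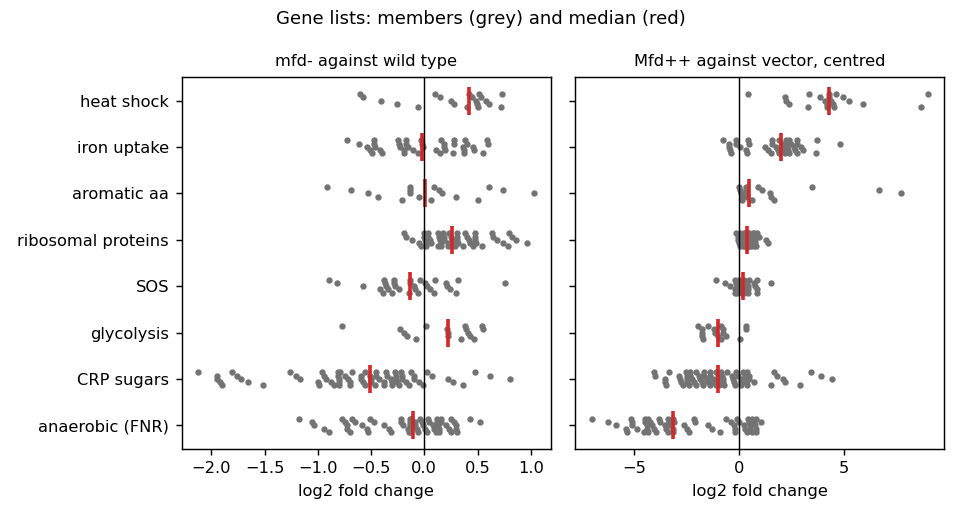
Log2 fold changes (horizontal axes) of the members of 8 gene lists (grey points) and their medians (red bars), in mfd- against wild type (left) and in Mfd++ against vector after centring on the median gene (right). The heat shock median is at 0.42 on the left and 4.30 on the right, and the FNR median at -0.11 and -3.14. The median over all genes tested is 0.18 on the right.

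The mfd- and Mfd++ comparisons were set against each other across genes to ask whether the same genes moved. The gene yhfY, risen in mfd- cells, stood at 13.7 ± 4.39 RPKM with vector and 4.88 ± 1.94 in Mfd++ cells (SD, n = 2 each), a log2 fold change of -1.33 (limma, adjusted p = 0.0223) that was 0.02 after centring. It did not pass without vector replicate 1 (limma, adjusted p = 0.0661), Mfd++ replicate 1 (0.204) or Mfd++ replicate 2 (0.412), or with the replicate number as a block (0.077). Across 4434 genes the log2 fold changes of the comparisons had Pearson's r = 0.18 and Spearman's rho = 0.211, and genes are not independent replicates. Taking a single library from each group gave 36 combinations, over which r ranged from -0.224 to 0.538 with an SD of 0.215. Without wild-type replicate 3, r was -0.02. Of 288 genes higher in mfd- cells in the authors' deposited table, 88 were higher in Mfd++ after centring, where independent lists would share 45.5 (Fisher's exact test, two-sided, adjusted p = 1.43e-09). By the same test 20 were lower, against 38.6 (adjusted p = 0.00366), and without centring 8 were higher, against 9.09 (adjusted p = 1), and 182 lower, against 157 (adjusted p = 0.0142). Of 58 genes lower in that table, 14 were lower in Mfd++ after centring, against 7.77 (adjusted p = 0.101). The authors' list rests on unadjusted p, and genes that share an operon do not count as separate draws. The overlaps were not recomputed without wild-type replicate 3, so they do not settle whether the same genes moved.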

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

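All alternatives that leave out replicate 3 of both groups, leave out the stretches without reads and ydbA, exchange replicate numbers or centre with a library left out were added after the data were seen, and the cause of each change below was not tested. In mfd- cells the 2 genes called became 9 without wild-type replicate 3, with 2 to 9 over single libraries left out, and 0 without replicate 3 of both groups, where mfd, at a log2 fold change of -4.56, and yhfY were not past the threshold. The authors' deposited test gave 351 genes unadjusted and 1 after Benjamini-Hochberg adjustment. Bins called ranged from 36 to 87 over single libraries left out and were 134 on the values as deposited. Lists called were 0 with an estimated correlation, 0 with fry, 6 to 14 over single libraries left out and 15 without replicate 3 of both groups. Ribosomal proteins turned downward without wild-type replicate 1 (adjusted p = 0.0717), with 7.52e-09 to 0.302 over single libraries left out.

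In Mfd++ cells the genes called fell from 2560 to 1296 with centring, 1452 with quantile normalisation and 1188 with centring and without the stretches and ydbA. Leaving out single libraries gave 2054 to 3460 genes uncentred and 959 to 1545 centred. Lists called were 0 with an estimated correlation and 8 to 17 over single libraries left out, and without vector replicate 2 colanic acid (adjusted p = 0.00659) and the Qin prophage (0.547) turned downward, with 0.00659 to 0.0703 and 0.00714 to 0.547 over single libraries left out. The correlation across genes of both comparisons ranged from -0.02 to 0.28. The log2 fold change of yhfY in Mfd++ cells turned to 0.018 with centring. Over all alternatives, values of single named genes other than mfd kept direction and side of the threshold in 693 cases in mfd- cells and 700 in Mfd++ cells, passed it newly in 8 cases in mfd- cells, and no longer passed in 1 and 16. Of these genes only yhfY was called in the fit of all libraries in mfd- cells. Most of the 693 cases are therefore genes that stayed short of the threshold.

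The replicate number as a block gave 2 genes, 35 bins and 9 lists in mfd- cells and 2288 genes and 14 lists in Mfd++ cells, with mfd at -4.26 and 1.19, and among lists called and genes named it ended only the call of yhfY in Mfd++ cells. Libraries with the same number deviated with correlations of 0.151, -0.329 and 0.256 in the first experiment, so not every library correlated best with its own number. Wild-type replicate 1 correlated best with mfd- replicate 2 (0.248), wild-type replicate 2 with mfd- replicate 1 (0.298), and replicate 3 with replicate 3. That pairing was not fitted in the first experiment. In the second the correlation was -0.349, and exchanged numbers, a crossed pairing, gave 148 risen and 2457 fallen genes and 13 lists. The planned test along genes was not run, for want of strand. The unknown depth of vector replicate 1 and its raised floor limit what can be said of genes below about 10 RPKM.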

Other observations

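The tests of the stretches without reads, of the shift of the median gene, of the aromatic and anaerobic genes and of the 10 splits of the mfd- experiment were set down after the results were seen. Single genes that the comparisons above do not describe changed in Mfd++ cells, in lists that camera did not call. Of the oxidative stress list 3 of 19 genes rose and 11 fell, or 8 and 2 after centring, and the 3 were marR, from 44.1 to 116 RPKM, marA, from 81.0 to 166, and marB, from 51.8 to 96.8 (means, n = 2 each), of the multiple antibiotic resistance operon. The rise of marB did not pass without vector replicate 1 (limma, adjusted p = 0.0588) or without the trend (0.0641). In the same list katG, of catalase, fell from 327 to 33.0 RPKM. Of the envelope stress list 3 of 20 genes rose and 17 fell, or 3 and 1 centred, and those risen included the periplasmic chaperone gene spy, from 33.3 to 235 RPKM, and cpxP, from 97.8 to 196. Of 7 sigma factor genes 2 rose and 4 fell, or 3 and 1 centred, and fliA, of the flagellar sigma factor, fell from 17.6 to 1.39 RPKM. The genes katG, spy and fliA were picked after their values were seen from those that the naming rule gives, the others lie outside that rule and were also chosen after their values were seen, and the preset adjusted p of their lists was 0.86, 0.983 and 0.549, while fry, which takes in the common shift, put the oxidative stress list (adjusted p = 0.0125) and the sigma factors (0.0448) lower before centring and 0 of the 3 lists past the threshold after it.

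Nearly all genes of the stretches from ycjQ to yncI and from elbB to yhcD lost their reads in both Mfd++ libraries, 88.8% of expressed genes against 2.84% elsewhere, a share partly set by how the stretches were found. The Mfd++ libraries, with like mfd levels (114 and 107 RPKM), kept unlike shares there, with a median log2 ratio of replicate 1 to replicate 2 of 2.39 (quartiles 1.55 and 2.83) over 76 genes of the stretches, against -0.03 (quartiles -0.38 and 0.30) over 89 other genes that fell below 5%, but these 76 genes held a median of 3.995 reads in replicate 2, and 51 of 1687 other fallen genes at 10 RPKM or more were also over 2-fold apart. So excess Mfd that lowers transcription of genes that are present cannot be told apart from a candidate explanation in which the stretches are missing from the chromosome of most Mfd++ cells: the reads left followed the vector level across genes, with correlations of 0.761 and 0.719, but so did those of the 89 other genes (0.815 and 0.677), as after any loss in proportion. Genes elsewhere at 20 RPKM or more with vector that kept under 1% of the vector level in replicate 2 and over 3 times as much in replicate 1 were borD, rzpD and rzoD of the DLP12 prophage and the neighbours cspD and clpS. DNA was not measured, and the source of the ydbA reads inside the long stretch was not tested.

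The lower median gene of the Mfd++ libraries, at -1.17, has a technical candidate explanation. With the reads of ydbA left out of the totals the median log2 fold change was -0.34, so that 71.2% of the shift was gone, since RPKM divides by all reads. The raised floor of vector replicate 1 alone cannot give the shift, since without that library the median was still -0.90. What remains of the shift is open, and no value here gives the RNA content of a cell.

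The rises of aroF and tyrA and the fall of FNR genes in Mfd++ cells may follow from the near absence of RNA of tyrR and fnr, which lie in the long stretch. Genes of the short stretch lost their reads in the same libraries, and their part in these changes was not tested. Of 9 genes known to be under TyrR, 3 had been noticed first and 5 are also on the aromatic synthesis list. Among the other 6, 4 rose after centring, with a median log2 fold change of 2.05 (uncentred 3 rose and 2 fell, median 0.70), against 3 of 13 aromatic synthesis genes outside TyrR control, with a median of 0.35 (uncentred 0 rose and 8 fell, median -0.99), and camera on the 6 TyrR genes gave p = 0.00157 preset and p = 0.174 with an estimated correlation. Of the 89 other genes below 5% of the vector level, 30 were on the FNR list. Excess Mfd acting with the stretch intact cannot be told apart from this explanation. In 0 Mfd++ libraries was the median gene of the stretches above 5% of its vector level.

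The log2 fold change of mfd itself was 1.19 (2.53 centred), against 8.71 (10.06 centred) for ydbA and 7.64 (8.99 centred) for ibpA, and no value here gives the Mfd protein level.

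The splits of the 6 libraries of the mfd- experiment into 3 and 3 number 10, too few for a share under 0.05. The real split called 2 genes and the highest of the others 0, and 1 split gave as many. For bins the real split called 39 and the highest other 6, with 1 split giving as many. At an unadjusted p under 0.05 (limma) the real split gave 404 genes and 3522 bins, and other splits reached 469 genes and 4368 bins. For lists called with the preset correlation the real split called 7 and the highest other 18, and 10 of 10 splits gave as many.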
